A study of Mus musculus with 36 samples.

How the data were processed

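Liver tissue of 36 C57BL/6 mice was sequenced with the QuantSeq 3' mRNA FWD kit and a module that adds unique molecular identifiers. The processing notes of the authors name UMI-tools 1.1.1, Trim Galore, STAR 2.7.9a, RSEM 1.3.1, DESeq2 and genome build GRCm39. The role and order of these tools, the versions of Trim Galore and DESeq2 and the annotation release are not given in the sources used here. The deposited table holds 29546 Ensembl gene IDs by 36 libraries, and its unit, signal, is gene counts that the authors divided by 1 factor per library, as DESeq2 size factors do. In every library the values were whole multiples of 1 step, within a tolerance of 0.001 read, so whole reads were recovered by dividing each library by its step. The recovered reads numbered 2081093 to 3770267 per library with a median of 2826073, and these totals set the precision of each value. IDs were matched to symbols in GENCODE M21, an annotation of GRCm38: 29121 had a symbol, 425 had none, and 29 duplicated symbols were left as IDs. Positions were not used.

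Libraries were grouped by their labels into 9 groups of 4, which are 6 treated and 3 control groups. The labels give no day for the controls, so each model's 4 controls served day 7 and day 28. Genes with a value of at least 10 in at least 4 of the 36 libraries were kept, which left 12596. limma 3.58.1 in R 4.3.3 was fitted to log2(normalized count + 1) with 1 coefficient per group over all 36 libraries, with the trend and robust options. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 within its contrast, and all tests were 2-sided. The contrasts were each treated group against its control, day 28 against day 7 of each model, the difference between the effects of 2 models at each day, the difference between the day changes of BDL and DDC, and an F test among the 3 control groups. Replicate numbers, which are those of the sample descriptions, were taken as different animals. The sample titles carry other numbers, and pairing by those was not tested as such. A check of whether equal numbers paired libraries found 0 pairs above a residual correlation of 0.1 in every contrast except BDL28 against BDL7, where 2 were above it.

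Gene lists were fixed before the data were examined, as were the contrasts, the filter, the tests and the rule for named genes. The 38 lists were bile acid synthesis, hepatocyte uptake transporters, canalicular exporters, basolateral exporters, bile acid receptors and their partners, cholangiocyte, fibroblast and matrix, Kupffer cell, monocyte and macrophage, neutrophil, T and NK cell, B and plasma cell, sinusoidal endothelial and hepatocyte markers, pericentral and periportal hepatocytes, CAR and PXR targets, NRF2 targets, acute-phase genes, cytokines with chemokines and adhesion genes, interferon response, cell cycle, cholesterol synthesis, lipogenesis, fatty acid oxidation under PPARA, endoplasmic reticulum stress, heme synthesis and breakdown, calcineurin and cyclophilins, p53 targets, YAP targets, the circadian clock, male-biased liver genes, urea cycle and amino acid metabolism, sex chromosome genes, red cell and platelet genes, pancreas, adipose and muscle, and mitochondrially encoded genes. Some genes stand in more than 1 list, and hepatocytes express many of the genes outside the lists of other cell types. Lists with at least 3 tested members (35) were tested with camera of limma, with a preset correlation of 0.01 between genes, over 210 tests of lists by comparison adjusted together, and again with an estimated correlation. List tests of the day contrasts and model differences were adjusted as a separate family and were chosen after the effects had been seen. The rule for named genes took 28 anchor genes in each effect contrast, called or not, then up to 5 highest and 5 lowest called genes per contrast whose libraries did not overlap and whose higher group averaged at least 50, and up to 4 members per described list with the lowest adjusted p. Symbols of predicted genes were left out of it. Some of the genes it took are not reported here, and 1 of these was left out of the search for single libraries far from their group. Genes named outside the rule are identified as chosen after their values were seen.

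A group with 0 reads of a gene was given a floor of 3 counts over the group, and the change is then a lower bound. The numbers of shared calls were compared with those of independent calls, and the effect of shared controls on correlations was simulated by regrouping residuals and by dividing the controls between the days. The tests were tested on simulated data made from the libraries with known changes. limma recovered 56% to 72% of genes changed 2-fold and 88% to 95% of genes changed 4-fold in the 6 effect contrasts, and camera called a shifted list of 20 genes and 0 of 37 unchanged lists. Of the genes limma called, 14 of 170 in BDL7, 9 of 169 in BDL28 and 4 of 148 in CsA7 had not been changed. In CsA28, DDC7 and DDC28 these were 9 of 159, 12 of 175 and 4 of 164. The simulated genes varied independently of each other. The camera result thus cannot show how often unchanged lists of correlated genes are called. Alternatives fixed before the data were examined were pseudocounts of 0.5 and 8, no filter, a mean of at least 50, quantile normalization, eBayes without the robust option, a fit of the contrast's groups alone, the 12 controls pooled, the replicate number as a block, edgeR 4.0.16 and DESeq2 1.42.0 on recovered reads, camera with an estimated correlation or a block, and each replicate left out in turn. Total-count scaling, leaving out VEHICLE replicates 1 and 2 together, and counts without the clock list and the Mup genes were added after the data were seen.

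T and NK cell markers and the pancreas list had 1 member each above the filter and the adipose and muscle list had 0, so these 3 lists had no list test. Transcript isoforms were left out because the values are per gene, and genomic positions because the builds differ.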

Results

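Liver RNA of 36 C57BL/6 mice was measured by QuantSeq, which sequences the 3' end of messenger RNA, with molecular identifiers that let copies made during amplification be counted once. The mice fell into 9 groups of 4. Bile duct ligation, which blocks bile flow surgically, was sampled at 7 days (BDL7) and 28 days (BDL28) with sham surgery as its control (SHAM). Cyclosporin A, an immunosuppressant that impairs bile secretion, was given by oral gavage and sampled at 7 days (CsA7) and 28 days (CsA28) with olive oil as its control (VEHICLE). A diet with 3,5-diethoxycarbonyl-1,4-dihydrocollidine (DDC), which injures bile ducts and causes porphyrin to accumulate, was sampled at 7 days (DDC7) and 28 days (DDC28) with a control diet (CTLD). The series calls the earlier day acute and the later day chronic cholestasis, and its title asks about conservation of the response. No day is given for the controls, so each model's 4 served both days.

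Group means of recovered reads ran from 2540604 in SHAM to 3339930 in CsA7, and 15816 to 18623 genes had at least 1 read. Values are mean normalized counts ± SD of 4 mice, and fold changes carry a standard error on the log2 scale. The median of a gene list is that of the log2 fold changes of its tested members. Bounds for groups without a read rest on a floor of 3 counts over the group and cover counting error only. Genomic positions are not given, because the builds differ. The identifiers of the genes reported in most detail are ENSMUSG00000028240 for Cyp7a1, ENSMUSG00000050445 for Cyp8b1, ENSMUSG00000041698 for Slco1a1, ENSMUSG00000032849 for Abcc4, ENSMUSG00000020911 for Krt19, ENSMUSG00000001506 for Col1a1, ENSMUSG00000026822 for Lcn2, ENSMUSG00000003849 for Nqo1, ENSMUSG00000038092 for Hsd3b5, ENSMUSG00000059824 for Dbp and ENSMUSG00000055116 for Arntl.

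**Figure D1:**
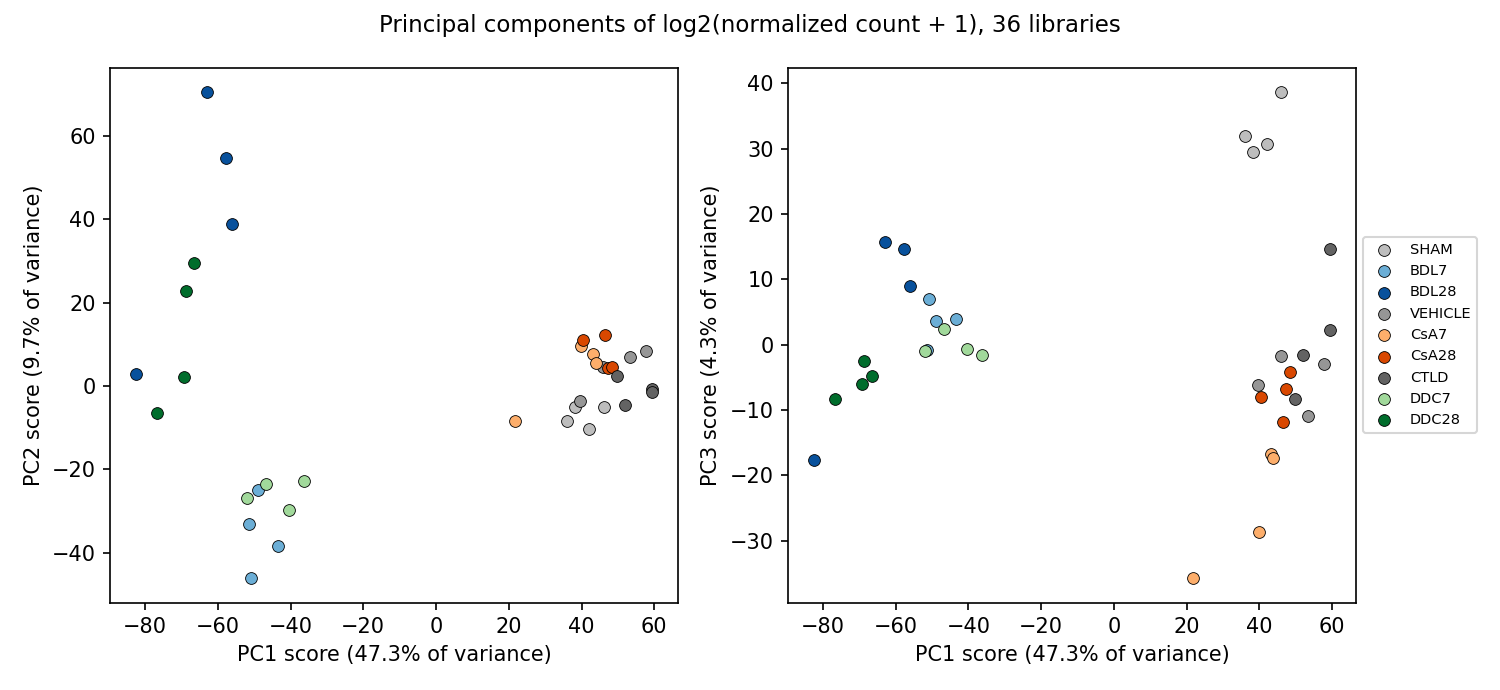
Principal components of log2(normalized count + 1) of the 12596 tested genes, 1 point per library, coloured by group, with 4 libraries per group and the percent of variance on each axis. The first component (47.3% of variance) separates the 16 BDL and DDC libraries from the 20 control and CsA libraries, and BDL28 replicate 1 stands apart from the other BDL28 libraries on the second (9.7%).

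The first comparison asked how the liver responds to 7 days of bile duct ligation. Genes of bile acid handling changed on the side of synthesis and of transport. Cyp8b1, the enzyme of the cholic acid branch, fell 16.7-fold, from 649 ± 67.5 in SHAM to 39.5 ± 13.7 in BDL7 (log2 -4.06 ± 0.34, limma adjusted p = 3.36e-10). Cyp7a1, the rate-limiting enzyme of bile acid synthesis, rose 3.76-fold, from 142 ± 54.5 to 555 ± 261 (log2 1.91 ± 0.54, adjusted p = 0.00612); its level was 260.1 ± 134 in VEHICLE and 359 ± 26.3 in CTLD. Slco1a1, an uptake transporter of the sinusoidal membrane, went from 1484 ± 71.2 to 10.3 ± 8.82 (log2 -7.44 ± 0.55). Abcc4, which exports bile acids back to the blood, went from 14.9 ± 2.02 to 46.9 ± 9.35 (log2 1.58 ± 0.32). The canalicular bile salt pump Abcb11 had a log2 fold change of -0.47 ± 0.19 and did not pass the test (adjusted p = 0.0529), though it did without BDL7 replicate 3 (-0.56) or 4 (-0.54) or SHAM replicate 2 (-0.53).

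Among 14 genes of bile acid synthesis 1 rose and 10 fell (the same adjusted over the list alone). Their median was -0.75 (camera adjusted p = 3.5e-06, and adjusted p = 0.13 with an estimated correlation). Scp2 fell by 1.12 ± 0.09 and Cyp7b1 by 3.33 ± 0.27 on the log2 scale. Of 7 uptake transporters 1 rose and 6 fell (the same adjusted over the list alone), among them Slc22a7 (-3.37 ± 0.38) and Slc10a1, the main bile salt uptake carrier (-1.58 ± 0.23). Their median was -1.16 (camera adjusted p = 0.00021, and adjusted p = 0.0293 with an estimated correlation). In the list of 4 basolateral exporters 4 rose and 0 fell (the same adjusted over the list alone), among them Slc51b (1.89 ± 0.31) and Abcc3 (0.79 ± 0.16). Their median was 1.68 (camera adjusted p = 0.0073, and adjusted p = 0.0722 with an estimated correlation). Of 8 canalicular exporters 3 rose and 2 fell (3 and 3 adjusted over the list alone), with camera adjusted p = 0.629. The bile acid receptor Nr1h4 (-0.33 ± 0.11) and its target Nr0b2 (-0.73 ± 0.29) fell, but neither was called with total-count scaling, and 0.0782 was the adjusted p of the list of receptors and their partners. Nr1h4 lost its call without BDL7 replicate 1 (-0.26) or without SHAM replicate 2 (-0.28), and Nr0b2 lost its call without any one of BDL7 replicates 1, 2 and 4 (-0.71, -0.62 and -0.64) and SHAM replicates 1 and 2 (-0.74 and -0.40).

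Markers of bile ducts, matrix and proliferation rose in BDL7. The cholangiocyte keratin Krt19 went from 2.12 ± 1.14 to 20.5 ± 6.35 (log2 2.81 ± 0.52), Krt7 was at least 16.3-fold higher, and of 15 cholangiocyte markers 13 rose and 0 fell (the same adjusted over the list alone). Their median was 2.81 (camera adjusted p = 8.46e-08, and adjusted p = 0.13 with an estimated correlation). Col1a1, a fibrillar collagen, went from 15.9 ± 0.762 to 366 ± 129 (log2 4.36 ± 0.40), and of 20 fibroblast and matrix genes 18 rose and 0 fell (19 and 0 adjusted over the list alone), among them Timp1 (4.36 ± 0.54) and Lox (4.19 ± 0.56). Their median was 2.47 (camera adjusted p = 3.01e-11, and adjusted p = 0.151 with an estimated correlation). In the cell cycle list of 18 genes 17 rose and 0 fell (the same adjusted over the list alone). Their median was 3.15 (camera adjusted p = 4.2e-07, and adjusted p = 0.218 with an estimated correlation). Mki67, a marker of dividing cells, went from 4.82 ± 0.871 to 57.1 ± 15.7. Of 10 p53 targets 6 rose and 0 fell (7 and 0 adjusted over the list alone). Their median was 0.71 (camera adjusted p = 0.00425, and adjusted p = 0.213 with an estimated correlation).

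Genes of inflammation and of the oxidative stress response rose as well. Lcn2, a secreted protein of acute injury, went from 7.42 ± 5.69 to 1681 ± 225 (log2 7.84 ± 1.18). Of 19 acute-phase genes 13 rose and 1 fell (14 and 3 adjusted over the list alone), among them Orm2 (4.50 ± 0.59). Their median was 1.21 (camera adjusted p = 0.000286, and adjusted p = 0.417 with an estimated correlation). Of 14 monocyte and macrophage markers 14 rose and 0 fell (the same adjusted over the list alone), among them Gpnmb (4.89 ± 0.55). Their median was 1.97 (camera adjusted p = 5.61e-10, and adjusted p = 0.13 with an estimated correlation). Trem2 was at least 17.2-fold higher. Marco (5.20 ± 0.49) was among the Kupffer cell markers, of which 4 rose and 0 fell (the same adjusted over the list alone). Their median was 0.93 (camera adjusted p = 0.00208, and adjusted p = 0.179 with an estimated correlation). Of the 6 neutrophil markers 5 rose and 0 fell (6 and 0 adjusted over the list alone). Their median was 2.39 (camera adjusted p = 0.0105, and adjusted p = 0.309 with an estimated correlation). With total-count scaling the adjusted p was 0.0644. Of 14 cytokine, chemokine and adhesion genes 10 rose and 0 fell (the same adjusted over the list alone). Their median was 2.42 (camera adjusted p = 5.01e-05, and adjusted p = 0.218 with an estimated correlation). Nqo1, a target of the oxidative stress factor NRF2, went from 11.1 ± 3.40 to 55.7 ± 14.2 (log2 2.25 ± 0.23), and of 16 NRF2 targets 14 rose and 1 fell (the same adjusted over the list alone). Their median was 1.64 (camera adjusted p = 1.18e-07, and adjusted p = 0.0722 with an estimated correlation).

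Hepatocyte genes with male-biased expression lay at the low end. Hsd3b5, a male-biased steroid dehydrogenase, went from 431 ± 72.2 to 0.254 ± 0.509 (1 read, log2 -8.48 ± 0.26). Elovl3 changed by -7.69 ± 0.57, and of 10 male-biased genes 0 rose and 10 fell (the same adjusted over the list alone). Their median was -4.04 (camera adjusted p = 3.91e-12, and adjusted p = 0.0184 with an estimated correlation). Of 16 hepatocyte markers 1 rose and 14 fell (the same adjusted over the list alone), among them Ttr (-1.35 ± 0.09). Their median was -0.67 in the authors' scaling and 0.004 after quantile normalization (adjusted p = 0.815). Camera gave adjusted p = 8.78e-08 in the authors' scaling, and adjusted p = 0.144 with an estimated correlation. Of 13 mitochondrially encoded genes 0 rose and 13 fell (the same adjusted over the list alone). Their median was -0.79 (camera adjusted p = 3.81e-08, and adjusted p = 0.218 with an estimated correlation). After quantile normalization the median was -0.10 (adjusted p = 0.138). Camera also called lower the lists of fatty acid oxidation (10 of 17 down, adjusted p = 0.00137, and adjusted p = 0.291 with an estimated correlation), urea cycle and amino acid metabolism (0.000464 and 0.309), pericentral hepatocytes (0.0106 and 0.322) and periportal hepatocytes (0.0164 and 0.291). Quantile normalization ended the calls of the last 3 lists (adjusted p = 0.263, 0.059 and 0.976) and turned the periportal median from -0.42 to 0.16.

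After Lcn2, the largest rises that the rule for named genes selected in BDL7 were those of the neutrophil attractant Cxcl5 (6.52 ± 1.17), the glutathione transferase Gsta1 (6.50 ± 1.21), Sprr1a (6.14 ± 0.74) and the metallothionein Mt2 (5.88 ± 1.15). The largest falls were those of Hsd3b5, Elovl3, Mup-ps17 (-7.59 ± 0.46), Slco1a1 and the sulfotransferase Sult2a8 (-6.41 ± 0.34). Hsd3b5 and Mup-ps17 had 1 read each in BDL7, so the added count of 1 limits their values. limma called 2549 genes higher and 2327 lower, of which 1449 and 469 changed by more than 1 on the log2 scale. The up share was 52.3% of called genes in the authors' scaling and 84.2% with total-count scaling (4922 up and 922 down), and the median log2 fold change of all genes was 0.326 against 0.011 in the authors' scaling.

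**Figure D2:**
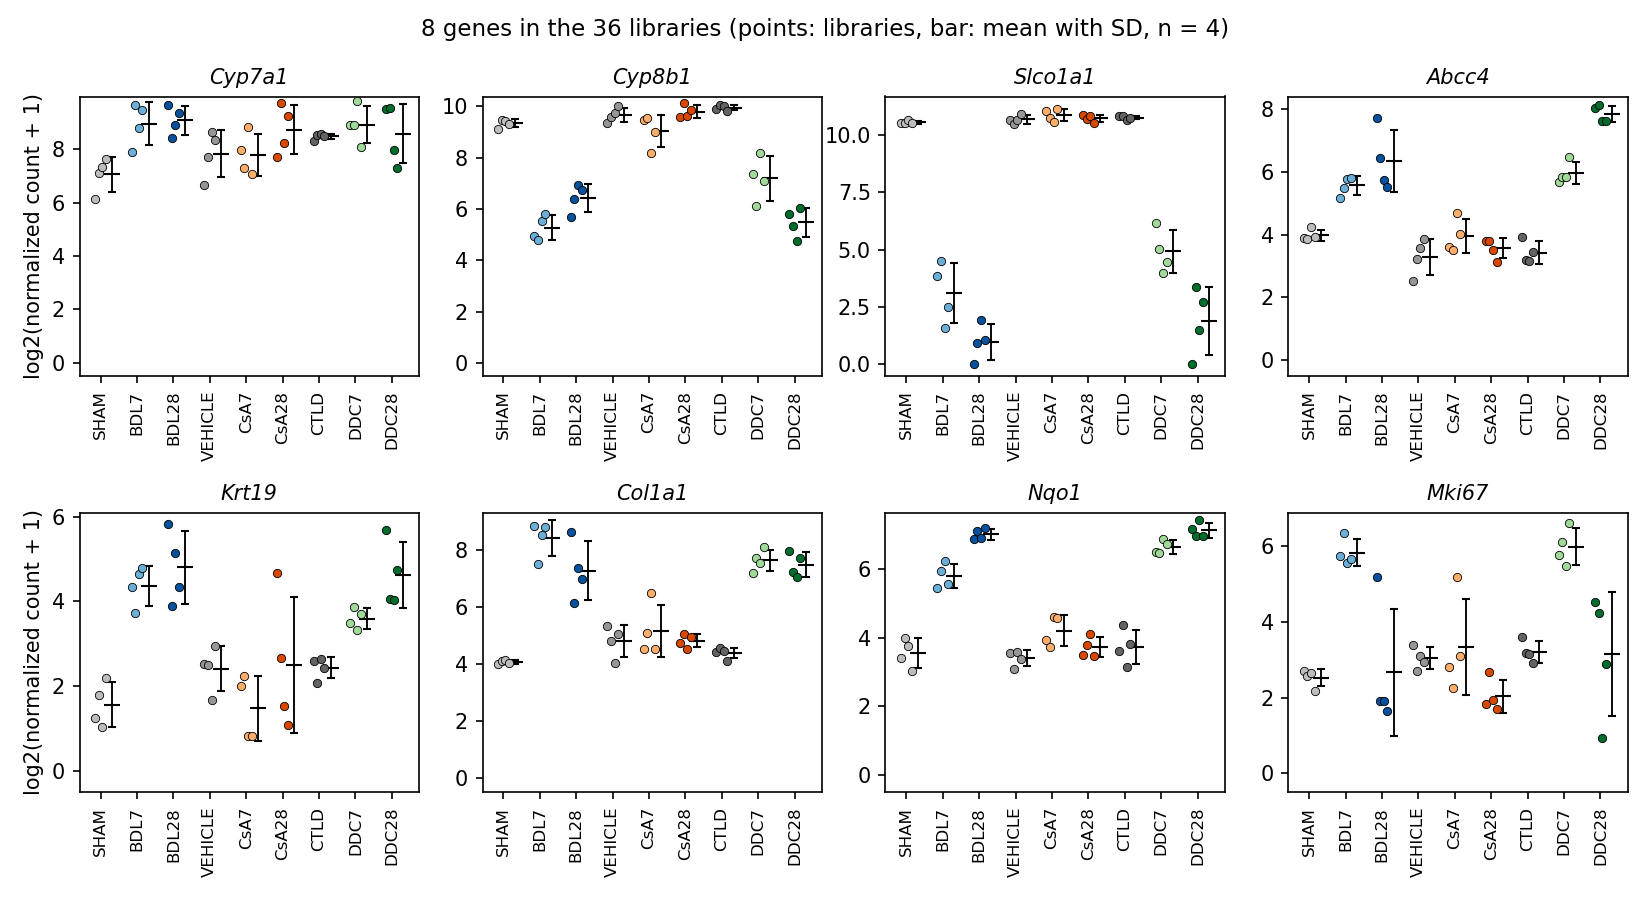
Log2(normalized count + 1) of Cyp7a1, Cyp8b1, Slco1a1, Abcc4, Krt19, Col1a1, Nqo1 and Mki67 in the 9 groups, with 1 point per library and the mean with SD of 4 libraries. Slco1a1 falls from a mean of 1484 normalized counts in SHAM to 10.3 in BDL7 and 1.19 in BDL28, Nqo1 rises from 11.1 to 55.7 and 128, and Slco1a1 averages 1621 in VEHICLE, 1855 in CsA7 and 1668 in CsA28.

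At 28 days the ligation comparison asked what the response is once cholestasis is chronic. Bile acid genes were again changed: Cyp8b1 was at 90.1 ± 30.5 (log2 -2.90 ± 0.34), Cyp7a1 at 573 ± 203 (2.03 ± 0.54, adjusted p = 0.00305), Slco1a1 at 1.19 ± 1.16 (-9.56 ± 0.55) and Abcc4 at 96.8 ± 74.6 (2.36 ± 0.32). Abcb11 fell from 996 ± 94.8 to 311 ± 109 (-1.75 ± 0.19, adjusted p = 8.68e-09). Slc10a1 fell by 0.61 ± 0.23, a call that ended without BDL28 replicate 1 (-0.28) or without SHAM replicate 2 (-0.62) or 3 (-0.55), and with total-count scaling. Of 14 genes of bile acid synthesis 2 rose and 9 fell (3 and 9 adjusted over the list alone). Their median was -0.79 (camera adjusted p = 0.000417, and adjusted p = 0.213 with an estimated correlation). Uptake transporters had a median of -1.52 (camera adjusted p = 0.000243, and adjusted p = 0.0293 with an estimated correlation), and basolateral exporters, of which 4 of 4 rose, had a median of 1.94 (camera adjusted p = 0.00618, and adjusted p = 0.0722 with an estimated correlation).

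Duct and matrix genes stayed above SHAM in BDL28. Of 15 cholangiocyte markers 12 rose and 0 fell (the same adjusted over the list alone), among them Cldn4 (4.57 ± 0.43) and Krt19, at 30.9 ± 18.9. Their median was 3.23 (camera adjusted p = 8.78e-08, and adjusted p = 0.13 with an estimated correlation). In the fibroblast and matrix list 13 rose and 0 fell (14 and 0 adjusted over the list alone). Their median was 1.23 (camera adjusted p = 0.00114, and adjusted p = 0.417 with an estimated correlation). Col1a1 was at 189 ± 144. Mki67 was at 10.8 ± 16.4 and not called (log2 0.14 ± 0.63), and without BDL28 replicate 1, at 35.4 against a nearest 2.79, the change was -0.70. Of 18 cell cycle genes 2 rose and 1 fell (0 and 0 adjusted over the list alone), with camera adjusted p = 0.699. NRF2 targets (16 tested) included Nqo1 (3.46 ± 0.23), and 12 rose and 1 fell (13 and 1 adjusted over the list alone). Their median was 1.57 (camera adjusted p = 2.96e-05, and adjusted p = 0.163 with an estimated correlation). Of 14 monocyte and macrophage markers 10 rose and 0 fell (the same adjusted over the list alone). Their median was 1.22 (camera adjusted p = 6.6e-05, and adjusted p = 0.291 with an estimated correlation). Neutrophil markers (adjusted p = 0.0345, and adjusted p = 0.403 with an estimated correlation), acute-phase genes (0.0421 and 0.655), cytokines (0.0483 and 0.522) and p53 targets (0.0421 and 0.318) were also called higher, and all 4 of these calls ended with total-count scaling (adjusted p = 0.117, 0.0687, 0.256 and 0.0915).

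Lower in BDL28 were genes of pericentral hepatocytes, lipid metabolism, interferon and the sinusoid. Glul, the glutamine synthetase of hepatocytes around the central vein, went from 2363 ± 163 to 468 ± 108 (-2.36 ± 0.21), and of 11 pericentral genes 0 rose and 11 fell (the same adjusted over the list alone). Their median was -1.56 (camera adjusted p = 2.99e-06, and adjusted p = 0.13 with an estimated correlation). Lipogenic genes numbered 13, of which 1 rose and 10 fell (the same adjusted over the list alone). Their median was -1.49 (camera adjusted p = 0.000156, and adjusted p = 0.195 with an estimated correlation). Of 17 fatty acid oxidation genes 0 rose and 11 fell (the same adjusted over the list alone). Their median was -1.14 (camera adjusted p = 0.000227, and adjusted p = 0.218 with an estimated correlation). Of 13 interferon response genes 0 rose and 9 fell (the same adjusted over the list alone), among them Isg15 (-1.84 ± 0.30) and Ifit1 (-2.32 ± 0.33). Their median was -1.38 (camera adjusted p = 0.000483, and adjusted p = 0.308 with an estimated correlation). Sinusoidal endothelial markers included Dnase1l3 (-2.14 ± 0.16), and of 14 markers 0 rose and 9 fell (the same adjusted over the list alone). Their median was -0.61 (camera adjusted p = 0.00102, and adjusted p = 0.242 with an estimated correlation). Of 16 endoplasmic reticulum stress genes 1 rose and 9 fell (the same adjusted over the list alone). Their median was -0.56 (camera adjusted p = 0.0423, and adjusted p = 0.49 with an estimated correlation). Quantile normalization ended the call (adjusted p = 0.126). Hepatocyte markers (-0.40, adjusted p = 0.00101, and adjusted p = 0.308 with an estimated correlation) and mitochondrially encoded genes (-0.42, 0.00532 and 0.508) lay lower in the authors' scaling, and quantile normalization turned both medians, to 0.13 and 0.06.

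Male-biased genes had a median of -5.59 (camera adjusted p = 2.75e-13, and adjusted p = 0.0184 with an estimated correlation) in BDL28, and all 10 fell. The major urinary protein gene Mup2, one of a family of near-identical copies among which reads are hard to assign, went from 9546 ± 1533 to 8.34 ± 11.8 (-11.23 ± 0.86), and Hsd3b5 was at least 591-fold lower. Rises at the high end included those of the estrogen sulfotransferase Sult1e1 (8.19 ± 0.70), Lrtm2 (7.68 ± 0.38) and Mt2 (6.54 ± 1.15). limma called 3037 genes higher and 2859 lower, 1326 and 940 of them by more than 1 on the log2 scale. With total-count scaling 4829 rose and 1672 fell (74.3% up against 51.5%), and the median log2 fold change of all genes was 0.289 against 0.034.

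The change from day 7 to day 28 of ligation was tested between BDL28 and BDL7 directly. The sulfotransferase Sult2a2 (6.25 ± 0.55) rose and Sult2a1 was at least 148-fold higher at day 28, while Mup13 (-6.88 ± 0.89), Mup2 (-6.25 ± 0.86) and the interferon-induced GTPase Tgtp1 (-5.48 ± 1.54) fell. Of 18 cell cycle genes 17 fell, among them Mki67 (-3.16 ± 0.63) and Top2a (-3.99 ± 0.63). Their median was -2.67 (camera adjusted p = 6.25e-08, and adjusted p = 0.219 with an estimated correlation). Of 13 interferon response genes 12 fell. Their median was -1.92 (camera adjusted p = 7.23e-10, and adjusted p = 0.142 with an estimated correlation). Matrix genes (13 fell, adjusted p = 3.68e-05, and adjusted p = 0.389 with an estimated correlation) and sinusoidal markers (11 fell, 1.46e-05 and 0.168) were also lower at day 28. limma called 1766 genes higher and 2105 lower, and without BDL28 replicate 2 the total was 2573 in place of 3871.

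The DDC comparison at 7 days asked how a toxic diet compares with ligation as a model of bile duct injury. Slco1a1 fell from 1708 ± 87.9 in CTLD to 34.6 ± 24.9 (log2 -5.82 ± 0.55), Cyp8b1 from 992 ± 69.7 to 165 ± 94.7 (-2.76 ± 0.34), and Abcc4 rose from 9.98 ± 2.94 to 62.2 ± 16.8 (2.53 ± 0.32). Cyp7a1 was at 531 ± 260.2 and not called (0.44 ± 0.54, adjusted p = 0.53). Cyp2b10, a target of the xenobiotic receptor CAR, rose 67.3-fold, from 13.3 ± 7.82 to 843 ± 175 (6.07 ± 0.88), while of 11 CAR and PXR targets 4 rose and 1 fell (the same adjusted over the list alone), with camera adjusted p = 0.163, but 0.00624 with quantile normalization (7 up). Fech, the last enzyme of heme synthesis, fell by 0.28 ± 0.09, and total-count scaling turned it to 0.07, while Hmox1, which breaks heme down, went from 89.5 ± 18.3 to 489 ± 76.0 (2.45 ± 0.27). The Fech call also ended without DDC7 replicate 4 (-0.23).

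Of 14 genes of bile acid synthesis 1 rose and 10 fell (the same adjusted over the list alone). Their median was -0.64 (camera adjusted p = 0.000306, and adjusted p = 0.203 with an estimated correlation). Uptake transporters had a median of -1.38 (camera adjusted p = 0.00417, and adjusted p = 0.101 with an estimated correlation), with 6 of 7 down and Slco1a4 up (2.46 ± 0.27). Basolateral exporters had a median of 2.31 (camera adjusted p = 0.00186, and adjusted p = 0.0355 with an estimated correlation), with all 4 up. Receptor genes (11 tested, 6 down) had a median of -0.51 (camera adjusted p = 0.0344, and adjusted p = 0.163 with an estimated correlation), but adjusted p = 0.0664 with total-count scaling. Of 15 cholangiocyte markers 9 rose and 0 fell (10 and 0 adjusted over the list alone). Their median was 1.75 (camera adjusted p = 0.000874, and adjusted p = 0.291 with an estimated correlation). Krt19, at 11.2 ± 2.04 against 4.47 ± 0.903, was not called (1.16 ± 0.52, adjusted p = 0.066). Of 20 fibroblast and matrix genes 15 rose and 0 fell (17 and 0 adjusted over the list alone), among them Col1a1 (3.25 ± 0.40). Their median was 1.43 (camera adjusted p = 1.47e-05, and adjusted p = 0.291 with an estimated correlation). Timp1 was at least 16.3-fold higher. In the cell cycle list 17 rose and 1 fell (the same adjusted over the list alone), among them Mki67 (2.78 ± 0.63) and Ccnb1 (5.28 ± 0.78). Their median was 3.27 (camera adjusted p = 1.2e-06, and adjusted p = 0.23 with an estimated correlation).

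NRF2 targets were also higher in DDC7: of 16 targets 14 rose and 0 fell (15 and 0 adjusted over the list alone), among them Nqo1 (2.91 ± 0.23), Srxn1 (2.76 ± 0.20) and Gsta2 (3.07 ± 0.25). Their median was 2.60 (camera adjusted p = 1.38e-10, and adjusted p = 0.0293 with an estimated correlation). Of 14 monocyte and macrophage markers 11 rose and 0 fell (13 and 0 adjusted over the list alone). Their median was 1.50 (camera adjusted p = 2.43e-06, and adjusted p = 0.218 with an estimated correlation). Gpnmb, a marker of lipid-laden macrophages, went from 1.48 ± 1.37 to 194 ± 23.4 (6.48 ± 0.55). Cytokines (12 of 14 up) had a median of 2.55 (camera adjusted p = 0.000194, and adjusted p = 0.268 with an estimated correlation). Kupffer cell markers (adjusted p = 0.00218, and adjusted p = 0.179 with an estimated correlation), neutrophil markers (0.0161 and 0.326) and p53 targets (0.00212 and 0.181) were also called higher; the neutrophil call ended with total-count scaling (adjusted p = 0.104).

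Lipogenic and protein-folding genes fell in DDC7. Of 13 lipogenic genes 0 rose and 10 fell (the same adjusted over the list alone), among them Thrsp (-2.95 ± 0.33). Their median was -0.97 (camera adjusted p = 8.94e-05, and adjusted p = 0.179 with an estimated correlation). Of 16 endoplasmic reticulum stress genes 2 rose and 10 fell (the same adjusted over the list alone), among them the chaperone Calr (-1.16 ± 0.12). Their median was -0.90 (camera adjusted p = 0.00131, and adjusted p = 0.291 with an estimated correlation). Male-biased genes had a median of -3.38 (camera adjusted p = 2.28e-09, and adjusted p = 0.0293 with an estimated correlation), with 9 of 10 down, and Hsd3b5 went from 526 ± 43.0 to 0.449 ± 0.525. Hepatocyte markers (-0.58, adjusted p = 2.31e-07, and adjusted p = 0.155 with an estimated correlation), mitochondrially encoded genes (-0.72, 3.13e-06 and 0.291), urea cycle genes (-0.43, 0.0305 and 0.522) and pericentral genes (-0.60, 0.0381 and 0.419) lay lower, calls that all ended with quantile normalization, which turned the hepatocyte median to 0.05. The highest named rises were those of Sprr1a (7.52 ± 0.74), Mt2 (7.28 ± 1.15) and the macrophage elastase Mmp12 (6.89 ± 0.85). limma called 3112 genes higher and 2779 lower, 1439 and 728 of them by more than 1 on the log2 scale. With total-count scaling 5575 rose and 1210 fell (82.2% up against 52.8%), and the median log2 fold change of all genes was 0.377 against 0.04.

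After 28 days of DDC diet Slco1a1 was at 4.14 ± 4.11 (log2 -8.85 ± 0.55), Cyp8b1 at 46.6 ± 17.1 (-4.46 ± 0.34), Abcc4 at 230.3 ± 42.9 (4.41 ± 0.32) and Abcb11 at 412 ± 119 (-1.07 ± 0.19), against the same CTLD libraries. Gpnmb reached 710.3 ± 110.2 (8.34 ± 0.55) and Mmp12 490.4 ± 106 (7.85 ± 0.85). Lrtm2 was at least 214-fold higher, while Mup2 fell to 11.6 ± 18.3 (-10.93 ± 0.86). Of 15 cholangiocyte markers 12 rose and 0 fell (the same adjusted over the list alone), among them Krt19 (2.19 ± 0.52) and Prom1 (4.15 ± 0.45). Their median was 2.98 (camera adjusted p = 6.66e-06, and adjusted p = 0.179 with an estimated correlation). In the matrix list 17 rose and 0 fell (19 and 0 adjusted over the list alone). Their median was 1.70 (camera adjusted p = 2.97e-05, and adjusted p = 0.308 with an estimated correlation). Mki67 was not called (-0.06 ± 0.63, and 0.68 without DDC28 replicate 3), and of 18 cell cycle genes 6 rose and 1 fell (3 and 1 adjusted over the list alone), with camera adjusted p = 0.172.

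Exporters and NRF2 targets were high at this day too. Basolateral exporters had a median of 2.64 (camera adjusted p = 0.00105, and adjusted p = 0.0293 with an estimated correlation), and NRF2 targets a median of 2.32 (camera adjusted p = 5.93e-08, and adjusted p = 0.0722 with an estimated correlation). Of the 16 NRF2 targets 14 rose, among them Nqo1, at 139 ± 22.2 against 12.9 ± 4.88, and the cystine carrier Slc7a11 (5.24 ± 0.56). Neutrophil markers had a median of 3.06 (camera adjusted p = 0.00348, and adjusted p = 0.291 with an estimated correlation), with S100a8 at 5.18 ± 0.77, and monocyte and macrophage markers had a median of 1.86 (camera adjusted p = 5.76e-07, and adjusted p = 0.203 with an estimated correlation). Of 14 cytokine genes 11 rose and 0 fell (the same adjusted over the list alone). Their median was 2.45 (camera adjusted p = 0.000909, and adjusted p = 0.291 with an estimated correlation). YAP targets (6 tested, 4 up) had a median of 1.19 (camera adjusted p = 0.0498, and adjusted p = 0.291 with an estimated correlation), and Kupffer cell markers a median of 1.09 (camera adjusted p = 0.022, and adjusted p = 0.291 with an estimated correlation). Total-count scaling ended both calls (adjusted p = 0.0933 and 0.0599).

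Of 10 male-biased genes 0 rose and 10 fell (the same adjusted over the list alone). Their median was -5.68 (camera adjusted p = 2.98e-12, and adjusted p = 0.0184 with an estimated correlation). Bile acid synthesis had a median of -0.77 (camera adjusted p = 0.000155, and adjusted p = 0.179 with an estimated correlation), and uptake transporters a median of -1.55 (camera adjusted p = 0.00157, and adjusted p = 0.0722 with an estimated correlation). Bile acid receptors had a median of -0.24 (camera adjusted p = 0.0343, and adjusted p = 0.163 with an estimated correlation), and total-count scaling turned this median to 0.13 (adjusted p = 0.0621). Glul fell to 451 ± 82.8 (-2.49 ± 0.21), and of 11 pericentral genes 0 rose and 7 fell (the same adjusted over the list alone). Their median was -1.41 (camera adjusted p = 0.00122, and adjusted p = 0.256 with an estimated correlation). Lipogenic genes (adjusted p = 0.000684, and adjusted p = 0.23 with an estimated correlation), endoplasmic reticulum stress genes (0.00303 and 0.314), fatty acid oxidation genes (0.00626 and 0.318) and sinusoidal markers (0.0407 and 0.424) were lower. Hepatocyte markers (-0.75, 9.77e-07 and 0.171), mitochondrially encoded genes (-0.82, 6.66e-06 and 0.291) and urea cycle genes (-0.52, 0.0149 and 0.482) were lower too, calls that ended with quantile normalization, as did that of fatty acid oxidation (adjusted p = 0.0564). limma called 3516 genes higher and 3117 lower, 1703 and 1076 of them by more than 1 on the log2 scale. With total-count scaling 5838 rose and 1602 fell (78.5% up against 53%), and the median log2 fold change of all genes was 0.386 against 0.037.

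Between the days of DDC diet, Cyp2b9 (4.47 ± 0.57) rose, Sult2a2 was at least 100-fold higher, and Mup2 (-6.98 ± 0.86) fell. Abcc4 rose by 1.89 ± 0.32 from day 7 to day 28. Of 18 cell cycle genes 13 fell. Their median was -2.44 (camera adjusted p = 3.01e-12, and adjusted p = 0.134 with an estimated correlation). Male-biased genes had a median of -1.71 (camera adjusted p = 2.14e-11, and adjusted p = 0.0288 with an estimated correlation), with 6 down, and cholangiocyte markers had a median of 1.04 (camera adjusted p = 2.19e-05, and adjusted p = 0.219 with an estimated correlation), with 3 up. limma called 261 genes higher and 457 lower, a total of 718 that was 351 without DDC28 replicate 3, 384 without DDC28 replicate 4 and 466 without DDC7 replicate 2.

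**Figure D3:**
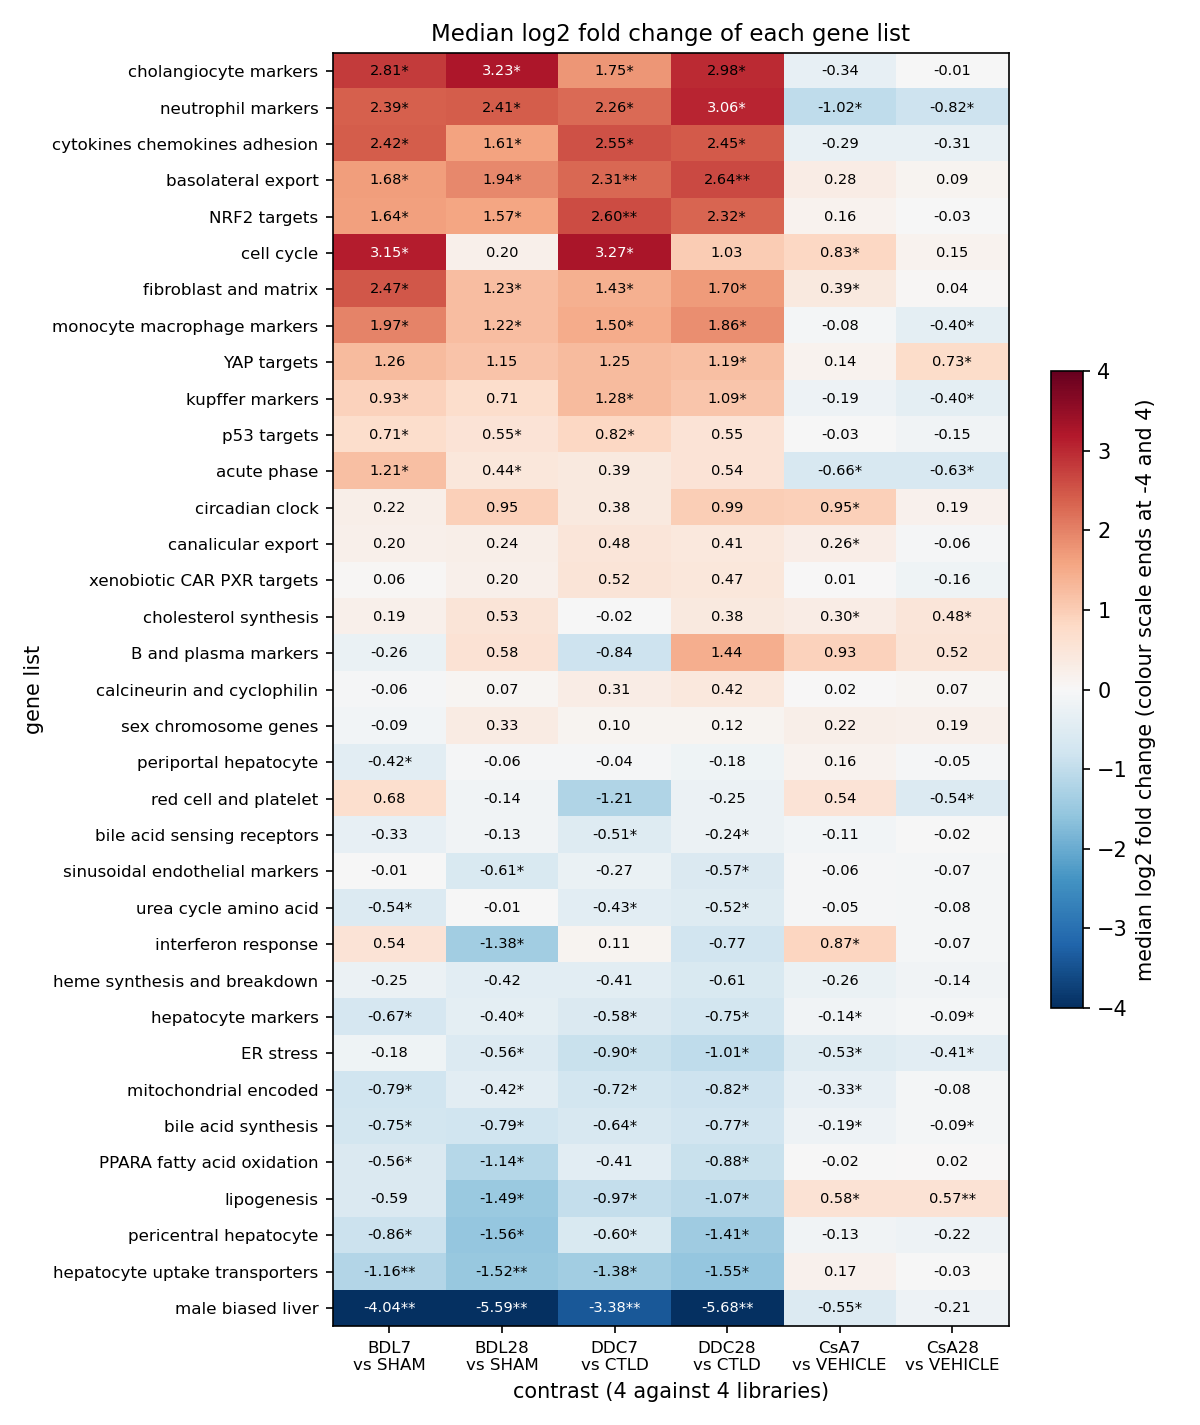
Median log2 fold change of the members of 35 gene lists (lines) in the 6 comparisons of a treated group with its control (columns), from 4 and 4 libraries each; 1 star marks camera adjusted p under 0.05 and a second star a call that also holds with an estimated correlation. Male-biased genes reach -5.59 in BDL28 and -5.68 in DDC28, and of the starred medians quantile normalization turns those of hepatocyte markers in BDL7, BDL28, DDC7, CsA7 and CsA28, periportal genes in BDL7 and mitochondrially encoded genes in BDL28, and total-count scaling that of bile acid receptors in DDC28.

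The cyclosporin A comparison at 7 days asked whether a drug that impairs bile secretion gives the response of the surgical and dietary models. Genes of the circadian clock were among those with the largest changes. Dbp, a clock output factor, rose 57.0-fold, from 3.41 ± 2.23 to 260.5 ± 133 (log2 5.83 ± 0.64, adjusted p = 1.48e-06), and Nr1d1, a clock repressor, went from 15.4 ± 7.76 to 84.5 ± 10.1 (2.54 ± 0.51). Arntl, the activator of the clock, fell from 136 ± 40.0 to 16.5 ± 17.3 (-3.66 ± 0.56), and Npas2 changed by -4.18 ± 0.47 and Nfil3 by -2.60 ± 0.36. Of 15 clock genes 7 rose and 5 fell (10 and 5 adjusted over the list alone). Their median was 0.95 (camera adjusted p = 0.00998, and adjusted p = 0.163 with an estimated correlation). The list moved in both directions, and its camera call ended with total-count scaling (adjusted p = 0.0933). The labels give no hour of collection.

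**Figure D4:**
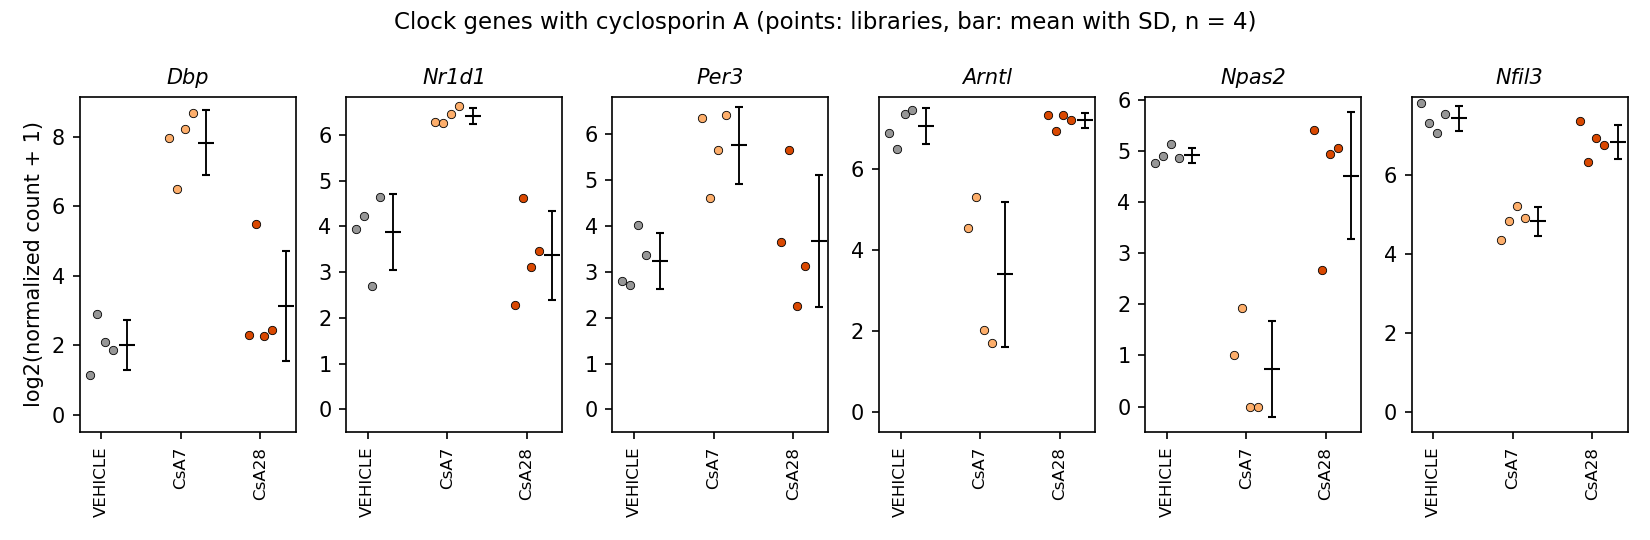
Log2(normalized count + 1) of Dbp, Nr1d1, Per3, Arntl, Npas2 and Nfil3 in VEHICLE, CsA7 and CsA28, with 1 point per library and the mean with SD of 4 libraries. Dbp averages 3.41 normalized counts in VEHICLE, 260.5 in CsA7 and 14.0 in CsA28, and Arntl 136, 16.5 and 147.

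Few bile acid genes changed in CsA7. Cyp7a1 (-0.05 ± 0.54), Cyp8b1 (-0.62 ± 0.34) and Slco1a1 (at 1855 ± 323 against 1621 ± 213) were not called. Of the 28 anchor genes Abcc2 (0.37 ± 0.10) rose and Sox9 (-1.13 ± 0.32) fell, and neither was called without VEHICLE replicates 1 and 2 (0.37 and -0.80). Abcc2 was not called without any one of VEHICLE replicates 1, 2 and 3 (0.38, 0.37 and 0.31) and CsA7 replicates 3 and 4 (0.32 and 0.32), nor Sox9 without any one of VEHICLE replicates 1 and 2 (-0.996 and -1.05) and CsA7 replicates 1, 3 and 4 (-1.16, -1.17 and -0.98). Of 8 canalicular exporters 4 rose and 0 fell (4 and 1 adjusted over the list alone), among them the sterol exporter Abcg8 (1.09 ± 0.20). Their median was 0.26 (camera adjusted p = 0.00682, and adjusted p = 0.13 with an estimated correlation). Of 14 bile acid synthesis genes Cyp7b1 alone fell (-1.34 ± 0.27). Their median was -0.19 (camera adjusted p = 0.00209, and adjusted p = 0.275 with an estimated correlation).

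Protein-folding genes lay lower and interferon and lipogenic genes higher in CsA7. Of 16 endoplasmic reticulum stress genes 1 rose and 7 fell (1 and 11 adjusted over the list alone). Their median was -0.53 (camera adjusted p = 3.45e-07, and adjusted p = 0.13 with an estimated correlation). The chaperone Hspa5 went from 5934 ± 733 to 3079.9 ± 378 (-0.95 ± 0.21), and Trib3, a kinase-like stress gene, rose (2.58 ± 0.43). Of 13 interferon response genes 3 rose and 0 fell (8 and 0 adjusted over the list alone). Their median was 0.87 (camera adjusted p = 3.23e-06, and adjusted p = 0.213 with an estimated correlation). Usp18 (1.60 ± 0.37) lost its call without CsA7 replicate 3 (1.31). Of 13 lipogenic genes 2 rose and 0 fell (8 and 0 adjusted over the list alone), among them Acaca, the first enzyme of fatty acid synthesis (0.83 ± 0.16). Their median was 0.58 (camera adjusted p = 8.92e-06, and adjusted p = 0.144 with an estimated correlation). Cholesterol synthesis (0.30, adjusted p = 0.000552, and adjusted p = 0.39 with an estimated correlation), cell cycle (0.83, 0.000268 and 0.326) and matrix genes (0.39, 0.0187 and 0.54) were called higher as lists with 0 members called, and the matrix call ended with either scaling alternative. Without VEHICLE replicates 1 and 2 the cholesterol synthesis (adjusted p = 0.118) and matrix (0.13) calls ended, and the cell cycle call stood (0.000254, but adjusted p = 0.637 with an estimated correlation). Male-biased genes (-0.55, 0.00135 and 0.218), hepatocyte markers (-0.14, 0.0305 and 0.49) and mitochondrially encoded genes (-0.33, 1.64e-05 and 0.308) lay lower; quantile normalization turned the hepatocyte median to 0.16 and ended the mitochondrial call (adjusted p = 0.526). The hepatocyte call also ended without VEHICLE replicates 1 and 2 (adjusted p = 0.0931).

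VEHICLE replicates 1 and 2 held 9848 and 7126 normalized counts of Saa1, an acute-phase protein, against 281 and 296 in the other VEHICLE libraries. Acute-phase genes in CsA7 had a median of -0.66 (camera adjusted p = 7e-12, and adjusted p = 0.179 with an estimated correlation), with 2 of 19 down and 17 down adjusted over the list alone, and without these 2 libraries the median was -0.04 (adjusted p = 0.968). Neutrophil markers, with 0 called, had a median of -1.02 (camera adjusted p = 0.0107, and adjusted p = 0.31 with an estimated correlation), and without these 2 libraries their median turned to 0.605 and the call ended (adjusted p = 0.265). With the preset correlation and without the 2 libraries the lists of interferon response (adjusted p = 8.43e-06), endoplasmic reticulum stress (8.88e-05), lipogenesis (0.0137), clock (0.0469) and canalicular export (0.0149) were still called. With an estimated correlation these 5 had adjusted p = 0.451, 0.451, 0.637, 0.451 and 0.249, and no list was called. limma called 237 genes higher and 270 lower in CsA7, 76 and 77 of them by more than 1 on the log2 scale. The total of 507 was 228 without CsA7 replicate 4, 303 without CsA7 replicate 3 and 347 without VEHICLE replicates 1 and 2, and with total-count scaling 699 genes rose and 140 fell (83.3% up against 46.7%), and the median log2 fold change of all genes was 0.131 against 0.002.

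After 28 days of cyclosporin A limma called no anchor gene and no clock gene. Dbp was at 14.0 ± 20.0 and Arntl at 147 ± 18.7. Cholesterol and fatty acid synthesis lay higher as lists: of 20 cholesterol synthesis genes 0 were called over all genes and 13 rose adjusted over the list alone. Their median was 0.48 (camera adjusted p = 1.33e-14, and adjusted p = 0.0815 with an estimated correlation). Of 13 lipogenic genes 6 rose adjusted over the list alone. Their median was 0.57 (camera adjusted p = 7e-12, and adjusted p = 0.0293 with an estimated correlation). Among their members Hmgcs1, which commits carbon to cholesterol, had log2 0.94 ± 0.21 and Fasn, the fatty acid synthase, 0.90 ± 0.20. Both passed the test without VEHICLE replicate 3 (1.06 and 1.09), and Hmgcs1 also without CsA28 replicate 3 (1.15). YAP targets (6 tested) had a median of 0.73 (camera adjusted p = 0.000417, and adjusted p = 0.0722 with an estimated correlation). Endoplasmic reticulum stress genes had a median of -0.41 (camera adjusted p = 0.00125, and adjusted p = 0.291 with an estimated correlation). Without VEHICLE replicates 1 and 2 the cholesterol (adjusted p = 2.51e-08), lipogenesis (3.27e-06) and endoplasmic reticulum stress (0.0108) calls stood with the preset correlation. With an estimated correlation they had adjusted p = 0.451, 0.249 and 0.673, so the lipogenesis call that held with all libraries ended (camera unadjusted p = 0.009). These values rest on fewer controls and were adjusted over the CsA7 and CsA28 lists alone, so they are not strictly comparable with those from all libraries.

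Acute-phase genes lay lower in CsA28 than in VEHICLE, with a median of -0.63 (camera adjusted p = 3.7e-12, and adjusted p = 0.17 with an estimated correlation). Neutrophil markers had a median of -0.82 (camera adjusted p = 0.0305, and adjusted p = 0.39 with an estimated correlation). Without VEHICLE replicates 1 and 2 both medians turned, to 0.10 (adjusted p = 0.0648) and 1.17 (adjusted p = 0.00251, and adjusted p = 0.249 with an estimated correlation). Monocyte and macrophage markers (-0.40, adjusted p = 9e-05, and adjusted p = 0.291 with an estimated correlation), Kupffer cell markers (-0.40, 0.00671 and 0.218) and red cell and platelet genes (-0.54, 0.037 and 0.417) also lay lower as lists, and these 3 calls ended without VEHICLE replicates 1 and 2 (adjusted p = 0.204, 0.568 and 0.148). Bile acid synthesis (-0.09, 0.0343 and 0.407) and hepatocyte markers (-0.09, 0.0392 and 0.514) were called with medians near 0, and both calls ended with total-count scaling. The hepatocyte call also ended without VEHICLE replicates 1 and 2 (adjusted p = 0.0736). limma called 3 genes, against 2 with edgeR, 71 with DESeq2 and 1174 at an unadjusted p under 0.05. They were the pseudogene Rps12-ps21 (3.19 ± 0.59), the uracil glycosylase gene Ung (-1.53 ± 0.29) and the adhesion gene Icam1 (-2.03 ± 0.38); Rps12-ps21 and Ung were named after their values were seen. Icam1 was not called without VEHICLE replicate 1 (-1.46) or 2 (-1.90), without both (-0.97) or without CsA28 replicate 1 (-1.95), 2 (-1.94) or 3 (-2.08). The count was 0 without VEHICLE replicate 1, CsA28 replicate 1 or CsA28 replicate 2, 1 without VEHICLE replicate 2, 7 without CsA28 replicate 4, and 36 without VEHICLE replicate 3. With total-count scaling 8 genes rose and 2 fell.

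Clock genes also changed between the days of cyclosporin A. Arntl (3.81 ± 0.56) rose and Dbp (-4.71 ± 0.64), Nr1d1 (-3.04 ± 0.51) and Tef (-1.54 ± 0.26) fell from day 7 to day 28, and of the 15 clock genes 5 rose and 6 fell. The immediate early genes Fos (3.75 ± 1.03) and Egr1 (3.52 ± 0.87) were among the largest rises. limma called 173 genes higher and 135 lower, a total of 308 that was 127 without CsA7 replicate 4 and 167 without CsA28 replicate 1.

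The shared part of the responses was counted among genes called in 2 comparisons with separate controls. At day 7, 1739 genes rose and 1531 fell in both BDL and DDC, where independent calls would give 629.8 and 513.4, and 74 moved in opposite directions against 1137.3. At day 28, 2103 rose and 2014 fell in both (847.7 and 707.5 for independent calls), and 97 were opposite. The correlation of log2 fold changes across genes, which are not independent replicates, was 0.783 at day 7 and 0.826 at day 28. CsA7 shared 72 rises and 104 falls with BDL7 (48 and 49.9 for independent calls; r across genes 0.183) and 106 rises and 142 falls with DDC7 (58.6 and 59.6; r 0.259). In all 4 BDL and DDC comparisons 1164 genes rose and 1209 fell. Between the days of a model the controls are shared, which alone gives a correlation of 0.481 in simulated unchanged groups; with the controls divided between the days, r across genes was 0.673 for BDL, 0.797 for DDC and 0.052 for CsA.

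Differences between models were tested as differences of their effects. At day 7 the acute-phase gene Orm2 had a higher effect in BDL than in DDC (3.99 ± 0.84, adjusted p = 0.00386), as had the lipid gene Srebf1 (2.18 ± 0.34), while Cyp2b10 (-5.58 ± 1.24, adjusted p = 0.00569) and the defensin Defb1 (-3.27 ± 0.50) had a lower one. At day 28 Cxcl13, a B cell attractant (4.11 ± 1.22), was higher in the BDL effect and Cyp2b10 (-5.31 ± 1.24), Mmp12 (-4.46 ± 1.20) and Sprr1a (-3.74 ± 1.05) lower. Endoplasmic reticulum stress genes had the higher effect in BDL at day 7, with a median of 0.89 (camera adjusted p = 0.000162, and adjusted p = 0.229 with an estimated correlation). CAR and PXR targets had the lower one, with a median of -0.49 (camera adjusted p = 0.000302, and adjusted p = 0.114 with an estimated correlation). Against the cyclosporin A effect at day 7, Slco1a1 was lower in BDL and DDC (-7.62 ± 0.78 and -6.01 ± 0.78), and at day 28 Slco1a1 was again lower (-9.60 ± 0.78 and -8.89 ± 0.78). Genes with different effects numbered 1065 for BDL against DDC at day 7 (476 higher in BDL) and 1295 at day 28 (591 higher), where the count was 2099 without BDL28 replicate 1 and 849 without BDL28 replicate 3. They numbered 2965 and 3761 for BDL against CsA and 3391 and 4480 for DDC against CsA, at day 7 and day 28. With total-count scaling the share with a higher effect in BDL than in DDC at day 28 was 27.9% against 45.6%, and the shares of BDL against CsA and DDC against CsA were 71.8%, 68.2%, 75.7% and 75.6% against 49.6%, 49.7%, 52.6% and 52%.

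SHAM differed from the other control groups. The retinoic acid hydroxylase Cyp26b1 was lower in VEHICLE than in SHAM (-4.24 ± 0.86, 32.2 ± 37.7 against 291 ± 167). An F test found 2449 genes that differed among the 3 groups. Pairwise tests, each adjusted by itself, called 2509 between VEHICLE and SHAM, 2006 between CTLD and SHAM and 8 between CTLD and VEHICLE.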

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

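Of the tests in this part, those without VEHICLE replicates 1 and 2, of clock genes between CsA28 and CsA7, of Ddx3y, of the gap between male-biased and hepatocyte genes, and of divisions that keep treated and control libraries apart were chosen only after the result was seen.

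The clock shift in CsA7 was set against 3 explanations. A shift of clock phase that other genes follow is consistent with the data: 81.4% of the 495 called genes outside the clock list had the sign of their covariation with the clock in 28 other libraries, against a median of 49.1% and a 95th percentile of 74.1% over 1000 shuffles. The VEHICLE libraries with high acute-phase transcripts are excluded as the cause, since 10 clock genes were still called without them. The signed clock mean above VEHICLE was 2.44, 1.66, 2.54 and 2.81 in the CsA7 libraries and 0, 1.24, 0.01 and 0.12 in CsA28. A drug effect on the clock that is the same at both days cannot alone make 11 clock genes differ between CsA28 and CsA7. With no hour given, a different hour of collection, with or without such an effect, and a drug action at day 7 stay open.

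The lower acute-phase transcripts in CsA7 may come from VEHICLE replicates 1 and 2, without which the median log2 fold change of the list was -0.04 (-0.039). The authors' scaling of the libraries is excluded as the cause, since the median was -0.52 (-0.522) with total-count scaling. Whether the mice of these 2 libraries were ill or were handled differently is not given in the labels, and no biological explanation was tested.

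The fall of male-biased genes in BDL and DDC was set against 3 explanations. Female animals under these labels are excluded: the lowest count of the Y-linked gene Ddx3y in the 16 BDL and DDC libraries was 419, against 349.7 in the controls, and Xist stayed at or under 1.45 in every library. A lower share of hepatocytes is excluded as the whole cause, since the median of the male-biased list lay below that of hepatocyte markers by 2.80 or more in each of the 4 comparisons (gap -2.80 at the smallest). Weaker growth hormone signalling in hepatocytes stays open: 1 of the 4 genes Igf1, Igfals, Socs2 and Cish, Igfals, was lower in all 4 comparisons, and Igf1 was lower in 3. Socs2 and Cish, with standard errors of 0.64 and 0.86 on the log2 scale, were too variable to show a 2-fold fall. Other regulators of male-biased genes were not tested and stay open too.

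Single libraries stood far from the other 3 of their group in 18 of 297 groups of 33 measures, where chance gives about 5%. In BDL28 replicate 1, Slc10a1 was at 287 normalized counts (nearest other 689), Epcam at 207 (69.7), Spp1 at 2118 (697) and Mki67 at 35.4 (2.79). In SHAM replicate 3, Slco1a1 was at 1591 (1457) and Abcc4 at 17.9 (14.2), and in VEHICLE replicate 4 Slc10a1 was at 1628 (1447). Sox9 was at 132 (215) in CTLD replicate 4. Lcn2 was at 1.01 (3.92, few reads) in CTLD replicate 1 and 38.8 (6.70) in CsA28 replicate 1. Timp1 was at 1.29, 2.39 and 1.38 (0) in replicate 1 of CsA28, VEHICLE and SHAM. Trem2 was at 0.951 (0) in CsA28 replicate 3. Reads in 1 library alone are always flagged, so these Timp1 and Trem2 flags raise the 18 and show no outlying library. In CsA28 replicate 2, Cyp3a11 was at 1304 (5868) and Cyp2b10 at 0 (18.1). Spp1 was at 929 (1300.0) in DDC7 replicate 1 and Hmox1 at 234 (310) in BDL7 replicate 4.

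Effects differed between days and models. BDL28 and BDL7 differed in 3871 genes, where 1 of 35 divisions of the libraries gave as many, the real one. That is the lowest share 35 divisions can give, so chance is made unlikely and not excluded. The next division called 2707 and put BDL28 replicate 1 with BDL7 replicates 1, 2 and 4, which points to a structure of the samples. CsA28 and CsA7 differed in 308 genes (highest other 66) and DDC28 and DDC7 in 718 (highest other 5), and for both only the real division of 35 gave as many. The day changes of BDL and DDC differed in 186 genes. For BDL against DDC, 1065 genes differed at day 7 and 1295 at day 28; 5 and 10 of 100 divisions that mixed all libraries gave as many, with highest others of 4947 and 5611, so chance cannot be excluded by these, and divisions that call several times the real count mix treated and control libraries and so point to that structure. With treated and control libraries kept apart, 1 of 100 gave as many at each day, with highest others of 666 and 797. For BDL against CsA, 2965 genes differed at day 7 and 3761 at day 28, with 3 of 100 mixed divisions as large at each day (highest others 3621 and 4151) and 2 and 1 with treated and control kept apart (4595 and 3651). For DDC against CsA, 3391 and 4480 differed, with 1 of 100 as large in each scheme at each day (highest others 2704 and 3589 mixed, 2 and 4151 kept apart). For these counts against CsA at most 3 of 100 divisions were as large in each scheme, the real one among them. Chance is thus unlikely but not excluded. The division that called 4595 exchanged all BDL7 and all CsA7 libraries and 1 control library of each model.

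Sox9, a transcription factor of bile duct cells, rose in BDL7 (1.03 ± 0.32) and fell in CsA7 (-1.13 ± 0.32). The difference was 2.17 ± 0.45 (limma adjusted p = 0.000736). The BDL7 call ended without BDL7 replicate 1 (0.80) or SHAM replicate 4 (0.84). The CsA7 call ended without any one of the libraries given above.

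The counts of the other comparisons were set against divisions of the same 8 libraries, 35 for each. Only the real division gave as many for BDL7 (4876 genes, highest other 2), BDL28 (5896, highest other 1313), CsA7 (507, highest other 15), DDC7 (5891, highest other 219) and DDC28 (6633, highest other 721). That is the lowest share 35 divisions can give, so chance is made unlikely and not excluded. For CsA28, 6 of 35 divisions gave as many as the 3 genes, with a highest other of 50 when VEHICLE replicates 1 and 2 stood together with CsA28 replicates 2 and 4, so chance cannot be excluded, and the larger count points to a structure of the samples. Among the 3 control groups 2449 genes differed, with 1 of 100 divisions as large, the real one, and a highest other of 403, which makes chance unlikely.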

How the results depend on the processing

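Total-count scaling, the counts without VEHICLE replicates 1 and 2 and the counts without the clock list and the Mup genes were tests chosen only after the result was seen. Named genes gave 574 results. Direction and side of the threshold were the same for 573 of them with pseudocount 0.5, 568 with pseudocount 8, 560 without a filter, 566 without the robust option, 569 with the replicate block, 540 with the contrast's groups alone, 536 with pooled controls, 555 with edgeR, 528 with DESeq2, 517 with quantile normalization and 527 with total-count scaling. Leaving out 1 replicate left 4400 results the same, 103 weaker, 33 stronger and 56 reversed. Of 210 list tests 96 lost their call with an estimated correlation, and 114 were the same, among them lists called with neither correlation. Calls that held included male-biased genes in BDL and DDC and uptake transporters in BDL. Also held were basolateral exporters in DDC, NRF2 targets in DDC7 and lipogenesis in CsA28. With the block 208 list tests were the same. The counts of BDL7 and of BDL28 against BDL7 were 4879 and 3856 with the block. Without the clock list and the Mup genes, every count stayed within 1.5 times its value, from 3 in CsA28 to 6588 in DDC28. These genes were only left out of the counts, without a new fit or adjustment. The result shows that they are a small part of each count and tests nothing more. Depth limits genes with few reads: a change from a group at 0 reads is given as a bound alone.

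Counts that moved by more than 1.5 times were these. With pseudocount 8, with a mean of at least 50, with quantile normalization and with the contrast's groups alone, CsA28 had 0 genes by limma, against 3 and 1174 at an unadjusted p. A mean of at least 50, which leaves 6791 genes to test, gave 3113 for BDL7 (35.2% up), 3817 for BDL28, 3798 for DDC7, 4144 for DDC28 and 2950 for DDC against CsA at day 28; fewer genes tested account for smaller counts. No filter gave 666 and 731 for BDL against DDC at day 7 and day 28. The contrast's groups alone gave 259 for CsA7, 2443 for BDL28 against BDL7, 161 for CsA28 against CsA7, 1114 for DDC28 against DDC7 and 645 for BDL against DDC at day 28. Pooled controls gave 1454 for CsA7 and 114 for CsA28, DESeq2 gave 71 for CsA28, and total-count scaling gave 839 for CsA7 and 10 for CsA28. Without VEHICLE replicates 1 and 2, CsA7 had 347 genes and CsA28 4, both within 1.5 times.

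Leaving out each replicate in turn gave 2573 to 4662 genes for BDL28 against BDL7, 127 to 352 for CsA28 against CsA7, 0 to 36 for CsA28, 228 to 489 for CsA7, 351 to 791 for DDC28 against DDC7 and 849 to 2099 for BDL against DDC at day 28. The ranges were 4297 to 4514 for BDL7, 5323 to 5699 for BDL28, 5172 to 5619 for DDC7, 6087 to 6372 for DDC28 and 1804 to 2521 among the controls.

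The log2 fold changes that changed sign were these, most of them not called. Pseudocount 8 gave 0.12 for Mki67 in DDC28. Quantile normalization gave 0.13 for F2 in BDL7, and -0.16 for Mki67, 0.14 for F2 and 0.21 for mt-Co3 in BDL28. It gave 0.018 for Abcb11, -0.038 for Slc51b, -0.24 for Krt7, -0.016 for Epcam, -0.14 for Trem2, 0.19 for Cyp3a11, 0.068 for Scp2, 0.05 for Trf, 0.11 for F2 and 0.18 for Ttr in CsA7, and 0.013 for Slc10a1, 0.012 for Ttr, 0.11 for Ahsg and 0.13 for F2 in CsA28. It gave 0.064 for Abcb11, 0.039 for Apoa1, 0.26 for Ass1 and 0.06 for mt-Nd5 in DDC7. Pooling the 12 controls gave -0.84 for Alas1 in BDL7, and -0.26 for Mki67 and -0.14 for Alas1 in BDL28. It gave 0.29 for Slc10a1, 0.042 for Abcc2, -0.002 for Abcc4, 0.049 for Timp1 and 0.13 for Lcn2 in CsA28, and -0.022 for Saa1 in DDC7. It gave -0.14 for Saa1, 0.22 for Mki67 and 0.025 for Alas1 in DDC28. edgeR gave -0.072 for Alas1 in BDL7, and 0.057 for Sox9, -0.022 for Col1a1 and 0.04 for Hbb-bt in CsA28. It gave 0.51 for Mki67 in DDC28. DESeq2 gave -0.046 for Alas1 in BDL7, and 0.045 for Sox9, -0.043 for Col1a1 and 0.018 for Hbb-bt in CsA28. It gave 0.51 for Mki67 in DDC28. Total-count scaling gave 0.015 for Fech in BDL28, and 0.082 for Cyp7a1, 0.11 for Abcb11 and 0.018 for Nr0b2 in CsA7. It gave 0.055 for Slc10a1 and 0.048 for Sox9 in CsA28, and 0.18 for Abcb11 and 0.072 for Fech in DDC7. It gave 0.25 for Mki67 in DDC28.

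Without VEHICLE replicates 1 and 2, CsA7 gave 0.008 for Abcb11, 0.088 for Nr0b2, -0.021 for Krt7, 1.14 for Lcn2, 0.24 for Saa1, 0.93 for S100a8, -0.046 for Fech, 0.35 for Hmox1, 0.25 for S100a9 and 0.28 for Mmp9. CsA28 gave -0.075 for Cyp8b1, -0.073 for Slco1a1, -0.15 for Abcc4, 0.30 for Sox9, 0.022 for Spp1, 0.30 for Timp1, 2.26 for Lcn2, 0.46 for Saa1, 1.42 for S100a8, -0.22 for Alas1, 0.028 for Hmox1, 0.003 for Cyp39a1, 0.13 for Cd163, 1.16 for S100a9, 1.19 for Retnlg and 0.025 for Hp.

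Leaving out each replicate in turn moved these genes across 0. In BDL7 the ranges were -0.064 to 0.64 for Alas1. In BDL28 the ranges were -0.70 to 0.48 for Mki67 and -0.40 to 1.40 for Cyp2b10. In CsA7 the ranges were -0.077 to 0.028 for Abcb11, -0.50 to 0.075 for Hmox1, -0.017 to 0.09 for Nr1h4, -0.17 to 0.13 for Krt7, -0.044 to 0.075 for Fech, -0.45 to 0.22 for Cyp7a1 and -0.12 to 0.25 for Slc51b. Also in CsA7 they were -0.27 to 0.48 for Trem2, -0.22 to 0.51 for Epcam, -0.30 to 0.04 for Nr0b2, -0.087 to 0.57 for Col1a1 and -0.32 to 0.66 for Mki67. In CsA28 the ranges were -0.35 to 0.11 for Sox9, -0.44 to 0.30 for Timp1, -2.01 to 0.019 for S100a8, -1.26 to 0.22 for Retnlg, -0.02 to 0.13 for Slco1a1, -0.016 to 0.34 for Alas1 and -0.069 to 0.22 for Nr0b2. Also in CsA28 they were -0.65 to 0.55 for Krt19, -0.24 to 0.19 for Col1a1, -0.087 to 0.028 for Slc10a1, -0.28 to 0.80 for Epcam, -1.53 to 0.084 for Cyp2b10, -1.19 to 0.02 for Hbb-bs and -1.19 to 0.13 for Hbb-bt. In DDC28 the ranges were -0.53 to 0.68 for Mki67 and -0.21 to 0.54 for Cyp7a1. Except for the filter, whose construction leaves fewer genes, the cause was not tested.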

Other observations

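List tests of the day contrasts, and tests of Cux2, Acot3, Cyp3a41a, Per1, Jchain and Igkc by name, were chosen only after the result was seen.

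Some genes known for higher expression in female mouse liver rose in BDL and DDC, and another did not. Cux2, a transcription factor of female mouse liver, was not called in BDL7 (1.02 ± 0.66) and had log2 rises of 5.09 ± 0.66 in BDL28, 2.41 ± 0.66 in DDC7 and 4.34 ± 0.66 in DDC28. The acyl-CoA thioesterase Acot3 rose by 2.79 in BDL7, 3.89 in BDL28, 2.78 in DDC7 and 3.83 in DDC28. Cyp3a41a, another female-biased gene, was not called in these 4 comparisons (0.23, 0.02, 0.53 and 0.20). Of the growth hormone targets, Igfals fell by 1.40 ± 0.19, 2.20 ± 0.19, 1.20 ± 0.19 and 1.58 ± 0.19, and Igf1 was lower in 3 of the 4 (-0.45 in BDL7, -0.98 in DDC7 and -0.84 in DDC28) with -0.15 in BDL28.

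Clock genes also differed between the days of the other models. From BDL7 to BDL28 7 of 15 clock genes rose, among them Per1 (2.84 ± 0.31). Clock genes had a median of 0.67 (camera adjusted p = 0.00282, and adjusted p = 0.134 with an estimated correlation) in that contrast. From DDC7 to DDC28 6 rose and 1 fell, and they had a median of 0.82 (camera adjusted p = 0.000472, and adjusted p = 0.077 with an estimated correlation). Against their controls, clock genes had camera adjusted p = 0.895 in BDL7, 0.0699 in BDL28, 0.941 in DDC7 and 0.224 in DDC28. That test reads 1 direction, and the list moved in both: 4 rose and 4 fell (5 and 5 adjusted over the list alone) in BDL7, 9 rose and 3 fell (the same adjusted over the list alone) in BDL28, 5 rose and 5 fell (the same adjusted over the list alone) in DDC7 and 8 rose and 4 fell (the same adjusted over the list alone) in DDC28. The immunoglobulin genes Jchain (2.92 ± 0.49) and Igkc (1.84 ± 0.45) rose from DDC7 to DDC28. Among interferon response genes 4 fell from DDC7 to DDC28, a minority of the list. The list median was -0.81 (camera adjusted p = 7.22e-07, and adjusted p = 0.219 with an estimated correlation).

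Several lists passed no camera test in the 6 comparisons with controls in the authors' scaling. Adjusted p ranged from 0.242 to 0.895 for B and plasma cell markers, from 0.0981 to 0.947 for CAR and PXR targets, from 0.0507 to 0.321 for heme synthesis and breakdown, from 0.355 to 0.873 for calcineurin and cyclophilins and from 0.0816 to 0.996 for sex chromosome genes. With quantile normalization CAR and PXR targets were called higher in DDC7 (adjusted p = 0.00624, 7 up) and DDC28 (0.0215, 8 up), and with total-count scaling sex chromosome genes were called higher in CsA7 (adjusted p = 0.0482). The median and the camera direction of CAR and PXR targets differed in sign in BDL7, BDL28 and CsA7, as did those of B and plasma cell markers and calcineurin genes in BDL28 and of clock genes in BDL7 and DDC7. The 1 pancreas gene above the filter fell by 1.73 in BDL7, 1.85 in BDL28, 2.09 in DDC7 and 1.81 in DDC28, and the 1 T and NK cell gene fell in BDL28 by 1.20; the adipose and muscle list had 0 genes above the filter.

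Normalized totals averaged 2442465 to 2550560 in the 4 BDL and DDC groups and 3057671 to 3213294 in the 3 control groups. Mitochondrially encoded genes held 5.01% to 8.67% of reads per library. An ID without a symbol, ENSMUSG00000119584, averaged 39487 normalized counts and held 0.813% to 1.93% of reads. VEHICLE replicates 1 and 2 also held the group's highest counts of Lcn2, up to 851.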
